A study of Mus musculus with 62 samples.

How the data were processed

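The series holds 62 Affymetrix mouse exon arrays of RNA from the right lower lung lobe of 48 male BALB/cJ and C57BL/6J mice, sensitised with Der p 1 and challenged with Der p 1 or PBS. Per the labels, arrays were grouped by strain and challenge into 4 groups, and the mouse numbers in the sample titles showed that 7 mice had 3 arrays each while every other mouse had 1. Mice were the unit of analysis, and the mean of a mouse's arrays was used. No values were used to decide the group of a mouse. The numbers of the mice begin with 5 or with 6 (series 5 and series 6); what sets these series apart is not given in the sources used here, and they were treated as a possible batch.

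The authors deposited log2 values per transcript cluster, made by RMA over core exons in Partek Genomics Suite, whose version is not given in the sources used here. The log2 base was checked against the range of the values, 1.27 to 13.8, with array medians of 6.39 to 6.62. The SD over clusters ranged from 1.44 to 2.09 between arrays. Raw intensities were not used here, so background, probe filtering and the masking of probes over strain polymorphisms could not be repeated. An array has no read depth; its precision was taken from repeat arrays of a mouse, where the median cluster had an SD of 0.190 on the log2 scale.

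Clusters were named with the platform's annotation: of 16715 clusters, 14959 carried 1 gene symbol, 1016 several and 740 none. Gene numbers of 14904 clusters were found in a mouse gene table, and 0 symbols changed. For gene lists the brightest cluster of each gene was kept, giving 14824 genes. Chromosome positions were not used here, since the array annotation names no genome build.

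A linear model with 1 mean per group was fitted to the values of the mice with limma 3.58.1 in R 4.3.3, with moderated t-tests. It gave 5 comparisons: challenged against control in each strain, the difference between these 2 changes, and BALB/cJ against C57BL/6J in controls and in challenged mice. P-values were adjusted by the method of Benjamini and Hochberg over all clusters within each comparison, and clusters with an adjusted p under 0.05 passed; counts with at least 1.5-fold are given beside. Genes named in the report are the 12 largest rises and 8 largest falls past the threshold of each challenge comparison, the 8 largest differences in each direction of each strain comparison, every gene past the threshold in the interaction, and members of the gene lists. Clusters with 1 symbol alone were named. No paired analysis was possible because each mouse gave 1 lung and the labels link no mouse of one group to a mouse of another.

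Gene lists were written before the values were examined, from textbook knowledge of lung cells and pathways: type 2 cytokines and receptors, mucous and goblet cell, alternatively activated macrophage, chemokines, eosinophil, mast cell and basophil, T cell, B and plasma cell, neutrophil, macrophage and monocyte, dendritic cell, NK and cytotoxic, club cell, ciliated cell, alveolar type II, alveolar type I, endothelial, smooth muscle, fibroblast and matrix, proliferation, interferon response, MHC class II, complement, airway contraction, eicosanoid, antioxidant, xenobiotic metabolism, circadian, immediate early, heat shock, heart muscle, skeletal muscle, adipocyte, erythroid and mesothelial. These 35 lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the data and the rotation test fry, with statmod 1.5.0, were run beside it. Some lists share members, so their calls are not separate evidence. For example, Ccl17, Ccl22 and Ccl24 were written into both the chemokine and the alternatively activated macrophage list. Lists of strain-specific and sex-linked genes served to check labels.

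Alternatives chosen before the data were examined were quantile normalization of the arrays again, centring of each array on its median, the first array of each mouse only, mouse as a random effect, leaving out the dimmest 25% or 50% of clusters, a trended and robust prior, array weights, fitting the compared groups only, the number series as a covariate, each number series alone, the first residual component as a covariate, the mean of a gene's clusters, and leaving out each mouse. Added after the data were seen were the fit without mouse633 and mouse634, that of the gene lists without mouse646 and mouse649, the SD of each array as a covariate, and their combinations with each other and with the number series. The clusters past the threshold in both strains were counted against the number expected from the 2 totals. For each comparison 100 groupings of the same mice were fitted, the real one included; for the interaction the residuals of an additive model were permuted. After the results were seen, 100 groupings that kept the number of mice of each group within each number series were fitted as well. The named calls, those of the 4 members with the smallest p of each gene list included, were followed through the alternative fits, and the called lists without each mouse and in each number series alone.

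The method was tested on simulated data in which 200 of 16715 clusters were changed by 1.5-fold, 2-fold or 4-fold. At 1.5-fold it recovered 74.6% in BALB/cJ, 61.2% in C57BL/6J, 43.3% in the interaction, 71.6% between controls and 82.1% between challenged mice; at 2-fold the shares were 95.5%, 97.0%, 89.6%, 98.5% and 92.5%. Calls among unchanged clusters numbered 8, 9, 6, 6 and 3. A shifted gene list was recovered with 0 other lists called. The simulated noise was drawn independently for each cluster, so this test cannot show list calls that arise from correlation between genes. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.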

Results

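RNA from the right lower lobe of the lung was measured in 48 male mice of 2 inbred strains, BALB/cJ and C57BL/6J, on 62 exon arrays. Every mouse was sensitised with Der p 1, a cysteine protease allergen of house dust mites, by intraperitoneal doses of 10 µg on days 1 and 8. On day 15 each mouse received 50 µg of Der p 1 (challenged mice) or PBS (controls), and lungs were taken on day 18. The groups held 11 control and 14 challenged BALB/cJ mice, and 11 control and 12 challenged C57BL/6J mice. Differences below are log2 ± standard error from limma over 16715 transcript clusters, group levels are mean ± SD over mice of the deposited log2 values, and p-values are adjusted over all clusters or over 35 gene lists. Mouse numbers began with 5 or with 6 (series 5 and series 6), and what sets these series apart is not given in the sources used here. Principal component 1 held 29.3% of the variance and followed the spread of each array's values (r = 0.952), with 38.6% of its variance between the number series. Challenge took up 38.8% and the number series 32.3% of component 2, and strain 75.8% of component 4.

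In BALB/cJ mice, the question was which lung transcripts differed 72 h after Der p 1 from those after PBS. Clca1, Chil4 and Rnase2a had the largest rises of single genes. Clca1 (transcript cluster 6910137), a product of goblet cells, rose from 6.59 ± 2.13 in 11 controls to 11.35 ± 1.59 in 14 challenged mice, by 4.76 ± 0.67 or 27.0-fold (adjusted p = 3.49e-05), and lay above the control mean in 13 of 14. Chil4, a chitinase-like protein, rose by 4.54 ± 0.76, and Rnase2a, an eosinophil-associated ribonuclease, by 3.69 ± 0.66. Retnla, a marker of macrophages activated by type 2 cytokines, was already bright in controls (9.84 ± 1.38) and rose by 2.88 ± 0.34 in 14 of 14 challenged mice (adjusted p = 6.31e-07). Ccl8 (2.88 ± 0.58), the chloride and bicarbonate exchanger Slc26a4 (2.86 ± 0.48), Bpifb1 (2.44 ± 0.56), the acute-phase gene Saa3 (2.39 ± 0.48), Agr2 (2.23 ± 0.40), Timp1 (2.14 ± 0.39), Chil3 (4.31-fold) and Tff2 (4.31-fold) completed the 12 largest rises. Without mouse633, a control with Clca1 at 12.6, the log2 differences were 5.36 for Clca1, 5.20 for Chil4 and 4.28 for Rnase2a. With mouse634 left out as well they were 5.73, 5.58 and 4.57, and those of Ccl8, Slc26a4 and Bpifb1 were 3.62, 3.52 and 3.04. Control levels of Chil4 (4.01 ± 2.26), Rnase2a (4.52 ± 2.03) and Ccl8 (4.76 ± 1.67) were low, and the deposited values do not tell background from low expression. The log2 differences of such genes are therefore those of the deposited values, no fold is printed for them, and the change of the transcript may be larger. Tff2 lost its call without mouse620 (adjusted p = 0.0536).

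The falls in BALB/cJ lungs were small. Hspa1a, an inducible heat shock protein, fell from 6.76 ± 0.66 to 6.03 ± 0.48 (1.66-fold, adjusted p = 0.0440) and lost its call without mouse633 and mouse634 (adjusted p = 0.0515). The prostaglandin receptor Ptgfr (−0.72 ± 0.19), the transporter Slc10a6 (−0.72 ± 0.19), the endothelial genes Esm1 (−0.71 ± 0.19) and Efnb2 (adjusted p = 0.0124, lower in 14 of 14), the matrix gene Ecm2 (−0.69 ± 0.18), Plscr4 (−0.58 ± 0.16) and 4930486L24Rik (−0.69 ± 0.18) fell as well. Of these 8 falls, Efnb2 kept its call whichever single mouse was left out. The calls of the others ended without 18 different mice for Hspa1a (highest adjusted p = 0.108, without mouse522), 13 for Plscr4 (0.0856, mouse620), 8 for Slc10a6 (0.0757, mouse619), 6 for Esm1 (0.0803, mouse619), 5 for 4930486L24Rik (0.0612, mouse522), 4 for Ecm2 (0.0576, mouse620) and 3 for Ptgfr (0.0575, mouse624). Hspa1a, Esm1 and 4930486L24Rik also lost their calls when BALB/cJ mice alone were fitted (adjusted p = 0.0766, 0.0835 and 0.0642), and Hspa1a with array weights (0.0543).

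In all, 323 of 16715 clusters passed, 284 higher and 39 lower after Der p 1, and 190 of the rises and 7 of the falls were at least 1.5-fold. Within series 5 alone 133 passed and within series 6 alone 0 passed by limma (1834 at an unadjusted p under 0.05), against 538 with the number series as a covariate. Series 6 holds mouse633 and mouse634, and 923 passed there without both. Single mice moved the count of 323 by more than 1.5-fold: it was 215 without mouse620, 614 without mouse633 and 504 without mouse634. Without mouse633 and mouse634 together it was 809, 555 higher and 254 lower, including 322 of the 323, so the share that was lower rose from 12.1% to 31.4%.

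**Figure D1:**
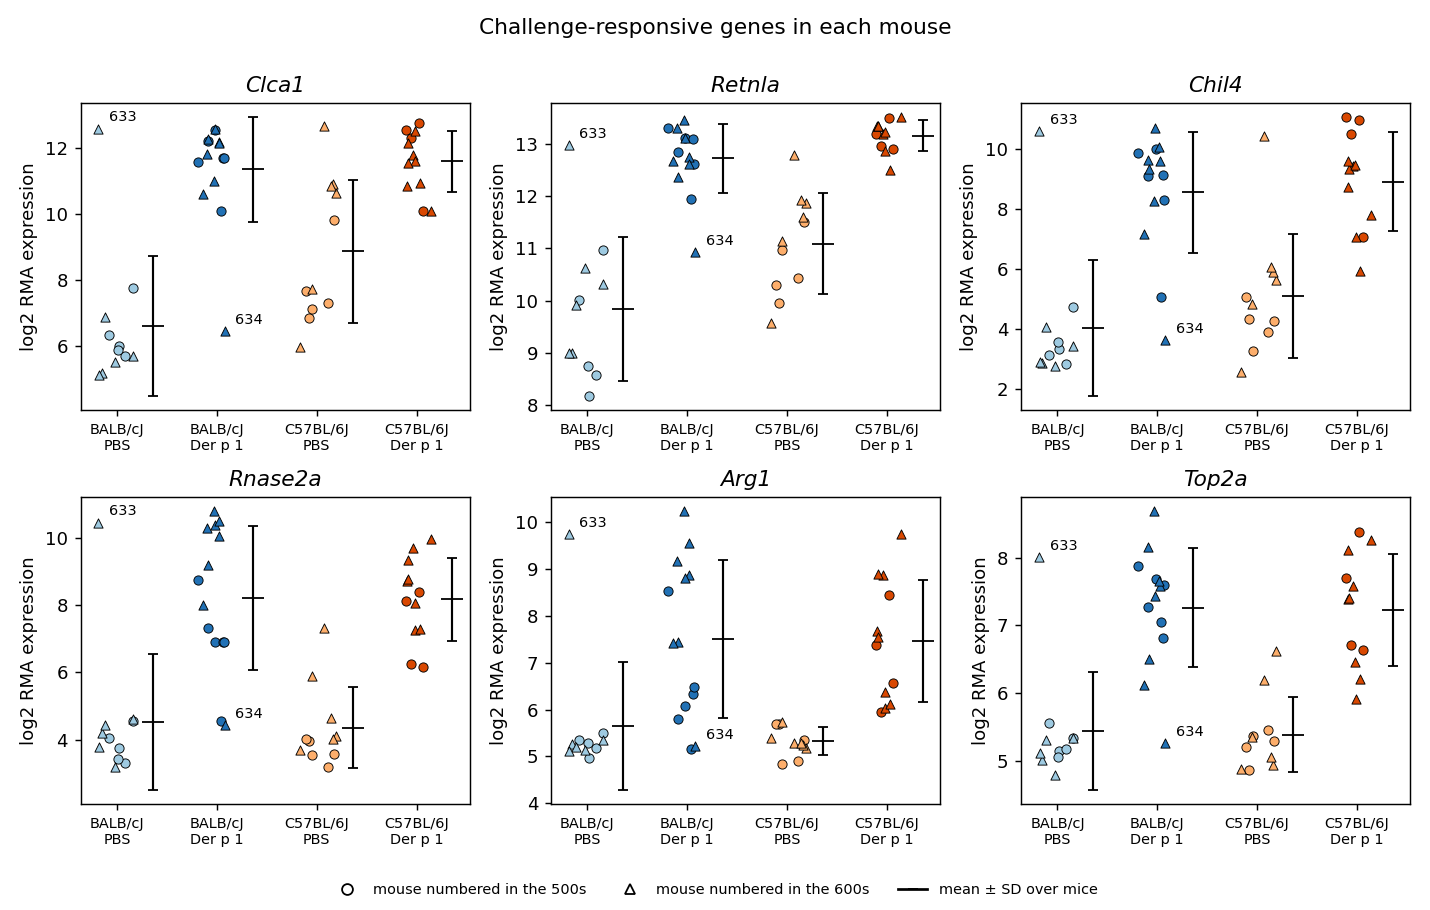
Deposited log2 values of 6 genes in each mouse, by strain and challenge; circles are mice of series 5, triangles mice of series 6, and bars the mean ± SD. Clca1 rose by 4.76 ± 0.67 in BALB/cJ and by 2.74 ± 0.69 in C57BL/6J (log2 ± standard error), and mouse633 and mouse634 are named.

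Cell division gave the smallest p of the lists in BALB/cJ. Of 23 proliferation genes, 20 rose and 0 fell (23 higher when adjusted over the list alone), with a median of 0.94 (adjusted p = 3.01e-45, and 0.00433 with an estimated correlation). Top2a rose by 1.82 ± 0.31, Ccna2 by 1.64 ± 0.25 and Aurkb by 1.03 ± 0.17, and the list's median was 0.85 in series 5 and 0.90 in series 6. Mucous and goblet cell genes rose in 8 of 15 (12 adjusted over the list alone, median 0.77, adjusted p = 2.31e-19, and 0.00433 with an estimated correlation). Alternatively activated macrophage genes rose in 7 of 15 (14 adjusted over the list alone), with a mean of 1.39 (median 0.64 in series 5 and 1.61 in series 6) and Mgl2 up by 1.52 ± 0.32 (adjusted p = 1.51e-22, and 0.00852 with an estimated correlation). Fibroblast and matrix genes rose in 8 of 16 (10 higher and 1 lower adjusted over the list alone), among them Eln (1.35 ± 0.24), Col1a1 (1.39 ± 0.32) and Col3a1 (1.16 ± 0.24). Their median was 0.55 (adjusted p = 4.92e-11, and 0.00993 with an estimated correlation).

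Genes of leukocytes and their signals shifted less firmly in BALB/cJ. Chemokine genes rose in 3 of 31 (12 adjusted over the list alone, median 0.31), with Ccl11 up by 1.47 ± 0.41 and Cxcl11 by 0.93 ± 0.25 (adjusted p = 5.88e-08, but adjusted p = 0.206 with an estimated correlation). Macrophage and monocyte genes rose in 3 of 17 (9 adjusted over the list alone, median 0.53, adjusted p = 7.95e-09, but adjusted p = 0.151 with an estimated correlation). Complement genes rose in 4 of 10, including C1qa (0.97 ± 0.23) and C1qc (0.94 ± 0.23) (median 0.40, 5 higher adjusted over the list alone, adjusted p = 2.93e-05, but adjusted p = 0.206 with an estimated correlation). C1qa, C1qb and C1qc were written into the macrophage and monocyte list as well, so these lists are not separate evidence. Eosinophil genes had a median of 0.39 with 1 of 9 higher (adjusted p = 0.00273, but adjusted p = 0.304 with an estimated correlation). Granule major basic protein, Prg2, was at 0.55 ± 0.28 and did not pass. Type 2 cytokine and receptor genes passed as a list with 0 of 18 passing singly (4 higher and 1 lower adjusted over the list alone, median 0.12, adjusted p = 0.0304, but adjusted p = 0.286 with an estimated correlation). Il13 was at 0.60 ± 0.19 and Il33 at 0.78 ± 0.29, neither past the threshold. T cell genes had 1 of 14 higher, Il2ra at 0.84 ± 0.22 (median 0.12, adjusted p = 0.00287, but adjusted p = 0.424 with an estimated correlation). MHC class II genes passed singly in 0 of 5 (2 higher adjusted over the list alone, adjusted p = 0.00242, but adjusted p = 0.286 with an estimated correlation). Without single mice the calls of Ccl11 (15 different mice, highest adjusted p = 0.0933 without mouse623), Cxcl11 (15 mice, 0.0739, mouse623) and Il2ra (8 mice, 0.0616, mouse514) ended.

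Which leukocyte lists were called differed between the number series, which by itself does not test a difference in response. A direct test with all mice, chosen after the values were seen, used camera. Chemokine (adjusted p = 5.3e-07), type 2 (0.000174), complement (0.00032) and eosinophil genes (0.000531) responded more in series 6. T cell (0.309) and MHC class II genes (0.0968) were not called. With an estimated correlation these 6 lists were not called (lowest adjusted p = 0.0617, type 2). In series 5 alone chemokine (median 0.14, adjusted p = 0.146), complement (0.26, adjusted p = 0.228), T cell (0.09, adjusted p = 0.119), MHC class II (0.28, adjusted p = 0.246), type 2 (−0.04, adjusted p = 0.758) and eosinophil genes (adjusted p = 0.656) were not called. In series 6 alone all 6 lists were called, with medians of 0.58, 0.40, 0.15, 0.55, 0.22 and 0.51. Macrophage and monocyte genes were called in both, at 0.25 and 0.62. The type 2 list lost its call without mouse621 (adjusted p = 0.0565), mouse635 (0.0742), mouse636 (0.0695) or mouse637 (0.0582).

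Genes of structural cells of the BALB/cJ lung shifted in both directions. Smooth muscle genes rose in 3 of 11, Actg2 by 0.98 ± 0.22, Acta2 by 0.69 ± 0.16 and Tagln by 0.42 ± 0.11 (median 0.34, 4 higher adjusted over the list alone, adjusted p = 3.6e-06, but adjusted p = 0.206 with an estimated correlation). Endothelial genes were lower in 1 of 15 (Tek, −0.44 ± 0.12; 3 adjusted over the list alone; median −0.17, adjusted p = 0.00124, but adjusted p = 0.286 with an estimated correlation). Alveolar type I genes were lower in 1 of 10 (Rtkn2, −0.47 ± 0.12; 3 lower adjusted over the list alone, adjusted p = 0.00175, but adjusted p = 0.291 with an estimated correlation). Ciliated cell genes had a median of 0.14 with 0 of 15 passing singly (adjusted p = 0.00793, but adjusted p = 0.458 with an estimated correlation). Of 25 eicosanoid genes, 2 were higher (median 0.05, Ptges up by 0.53 ± 0.14; 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00793, but adjusted p = 0.286 with an estimated correlation). Immediate early genes had a median of −0.23 with 0 of 13 passing (1 lower adjusted over the list alone, adjusted p = 0.00549, but adjusted p = 0.386 with an estimated correlation). Fat cell genes had a median of −0.29 with 0 of 7 (adjusted p = 0.00357, but adjusted p = 0.286 with an estimated correlation). Without single mice the calls of Tek (15 different mice, highest adjusted p = 0.0869 without mouse528), Tagln (12 mice, 0.0837, mouse620), Rtkn2 (6 mice, 0.0625, mouse621) and Ptges (4 mice, 0.0620, mouse521) ended.

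Ciliated and fat cell genes were called in series 5 and not in series 6. Ciliated cell genes were at 0.44 in series 5 (adjusted p = 2.04e-11) and −0.03 in series 6 (adjusted p = 0.764), and this difference was called with an estimated correlation as well (−0.38, adjusted p = 0.0379). Fat cell genes were at −0.60 in series 5 (adjusted p = 7.15e-07) and −0.03 in series 6 (adjusted p = 0.801), a difference of 0.57 (adjusted p = 1.09e-05, but adjusted p = 0.0735 with an estimated correlation). The median of ciliated cell genes was 0.09 without mouse517, and that of fat cell genes −0.18 without mouse522. In series 5 endothelial (−0.23, adjusted p = 0.0819), eicosanoid (−0.05, adjusted p = 0.64) and immediate early genes (−0.16, adjusted p = 0.146) were not called, and in series 6 they were (−0.21, 0.20 and −0.20). Alveolar type I genes were at −0.28 in series 5 and −0.15 in series 6, where they were not called (adjusted p = 0.0924). The eicosanoid median of 0.05 was 0.03 without mouse525, mouse621 or mouse631, and 0.09 without mouse524, mouse528 or mouse624.

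The other 17 lists were not called in BALB/cJ. Among them the medians were 0.11 for mast cell and basophil (0 of 11 higher), −0.12 for B and plasma cell (0 of 16), 0.18 for dendritic cell (0 of 11) and −0.04 for NK and cytotoxic genes (0 of 10). Neutrophil genes had 0 of 12 passing, a median below 0 and a mean of 0.11. Interferon response genes had a median of 0.09 (0 of 17, adjusted p = 0.0501), airway contraction genes −0.04 (0 of 26), club cell genes −0.06 (0 of 11), and alveolar type II genes 0.08 with Sftpd up by 0.37 ± 0.10. Hmox1 rose by 0.92 ± 0.24 among 16 antioxidant genes (median 0.10), and Gsto1 by 0.92 ± 0.22 and Cyp1b1 by 0.49 ± 0.12 among 15 xenobiotic metabolism genes (median −0.31, with 2 higher and 5 lower adjusted over the list alone). Circadian genes had a median of −0.14 (0 of 11), heat shock genes −0.33 (1 of 5 lower), and genes of heart muscle 0.11, skeletal muscle −0.05 with Acta1 up by 0.76 ± 0.21 and a mean of 0.04, erythroid cells −0.15 and mesothelium 0.16. Without single mice the calls of Acta1 (15 different mice, highest adjusted p = 0.0984 without mouse619), Hmox1 (7 mice, 0.0726, mouse631), Sftpd (6 mice, 0.0605, mouse513) and Cyp1b1 (0.0507, mouse631 alone) ended.

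In C57BL/6J mice the same question was asked of 12 challenged against 11 control lungs. Rnase2a and Chil4 had the largest rises of single genes, and Sult1d1 and Pon1 the largest falls. Rnase2a rose from 4.36 ± 1.21 in controls to 8.16 ± 1.25, by 3.81 ± 0.68 (adjusted p = 2.28e-04, 12 of 12 challenged mice above the control mean). Chil4 rose by 3.80 ± 0.79, Saa3 by 3.26 ± 0.50, Slc26a4 by 3.26 ± 0.50, the eosinophil-attracting chemokine Ccl24 by 2.83 ± 0.47, Ccl8 by 2.68 ± 0.60 and the macrophage elastase Mmp12 by 2.62 ± 0.53. Clca1 rose by 2.74 ± 0.69 from a control level of 8.86 ± 2.18. Pdcd1lg2 (2.27 ± 0.46), Alox15 (2.22 ± 0.45), AA467197 (2.19 ± 0.35) and the arginine-degrading enzyme Arg1 (2.14 ± 0.52) were the other 4 of the 12 largest rises. In series 6 alone Clca1 (1.65, adjusted p = 0.221) and Chil4 (2.52, adjusted p = 0.0974) did not pass, and in series 5 alone Ccl8 (2.14, adjusted p = 0.0563) and Arg1 (1.79, adjusted p = 0.0667) did not.

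The falls in C57BL/6J lungs were led by the sulphotransferase Sult1d1, from 7.51 ± 1.09 to 5.25 ± 0.97 (−2.27 ± 0.39, adjusted p = 1.51e-04, lower in 12 of 12). Paraoxonase Pon1 fell to 7.62 ± 1.12 (−1.77 ± 0.36, lower in 11 of 12), the muscarinic receptor Chrm2 by 2.75-fold, and Pln, a calcium pump regulator of muscle, from 7.30 ± 1.19 to 5.95 ± 0.83 (adjusted p = 0.0169). Galnt15 (−1.35 ± 0.23), Abca8a (−1.28 ± 0.21), Cyp2e1 (−1.26 ± 0.24) and the proteoglycan Dcn (−1.31 ± 0.30) fell too, the last to −0.82 with the spread of each array as a covariate. Pln did not pass in either series alone, and Sult1d1 (−1.40), Chrm2 (−1.35), Dcn (−1.45) and Cyp2e1 (−1.39) did not pass in series 5 alone. Altogether 3146 clusters passed, 1646 higher and 1500 lower, of which 431 and 357 were at least 1.5-fold. The share that was lower, 47.7%, was 66.8% with each array centred on its median. In series 5 alone, 305 passed, in series 6 alone, 4069, and 5480 with the number series as a covariate; without mouse531 the count was 4969. Challenged C57BL/6J arrays had a mean SD over clusters of 1.86 ± 0.15 against 1.96 ± 0.11 in controls, and with array SD as a covariate 2279 clusters passed.

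Cell division genes rose in 19 of 23 in C57BL/6J (21 adjusted over the list alone, median 0.90), with Ccna2 up by 1.65 ± 0.26 and Tpx2 by 1.45 ± 0.25 (adjusted p = 7.34e-15, but adjusted p = 0.275 with an estimated correlation). Alternatively activated macrophage genes rose in 14 of 15, Retnla by 2.06 ± 0.35 (median 1.23, adjusted p = 1.2e-08, but adjusted p = 0.275 with an estimated correlation). Mucous and goblet cell genes rose in 7 of 15 (9 adjusted over the list alone), Agr2 by 1.73 ± 0.41 and Foxa3 by 0.55 ± 0.12 (median 0.66, adjusted p = 2.29e-05, but adjusted p = 0.275 with an estimated correlation). Chemokine genes were higher in 16 and lower in 1 of 31, Cxcl10 up by 1.71 ± 0.29 (median 0.53, 19 higher and 1 lower adjusted over the list alone, adjusted p = 2.03e-05, but adjusted p = 0.275 with an estimated correlation). Eosinophil genes rose in 6 of 9, Prg2 by 1.40 ± 0.29 (median 0.78, 7 higher adjusted over the list alone, adjusted p = 0.000116, but adjusted p = 0.275 with an estimated correlation). T cell genes rose in 9 of 14, Cd3e by 0.62 ± 0.13 and Lat by 0.65 ± 0.14 (median 0.43, 11 higher adjusted over the list alone, adjusted p = 1.19e-05, but adjusted p = 0.275 with an estimated correlation). Macrophage and monocyte genes rose in 6 of 17 (Itgam, 0.91 ± 0.24; median 0.40, 7 higher adjusted over the list alone, adjusted p = 0.0165, but adjusted p = 0.58 with an estimated correlation). In series 5 alone chemokine (0.21, adjusted p = 0.0623), eosinophil (0.29, adjusted p = 0.0534) and macrophage and monocyte genes (0.20, adjusted p = 0.288) were not called, and in series 6 alone they were, at 0.74, 1.04 and 0.49. Mucous and goblet cell genes were at 0.95 in series 5 and 0.42 in series 6. Macrophage and monocyte genes lost their call without mouse531 (adjusted p = 0.0886).

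Interferon-stimulated genes rose in 10 of 17 in C57BL/6J (13 adjusted over the list alone), among them Mx1 (1.25 ± 0.27), Irf7 (0.95 ± 0.22) and Oas2 (0.76 ± 0.16). Their median was 0.60 (adjusted p = 7.87e-06, but adjusted p = 0.313 with an estimated correlation), with 0.25 in series 5 and 0.74 in series 6. As a score over the list, mouse646 (2.14) and mouse649 (1.35) stood apart from the other 10 challenged mice (−0.18 to 0.74). Without these 2 mice 8 of 17 rose, with a median of 0.37 (adjusted p = 0.000619, but adjusted p = 0.364 with an estimated correlation), and Mx1 was at 0.86, Irf7 at 0.61 and Oas2 at 0.55. Type 2 genes did not pass as a list (5 of 18 higher, median 0.14, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.176), while Il13 rose by 0.92 ± 0.20, Il4 by 0.68 ± 0.20 and Il5ra by 0.56 ± 0.15. Xenobiotic metabolism genes fell in 11 of 15, Aldh3a1 at −1.26 ± 0.20 and Ephx1 at −1.13 ± 0.21 (median −0.76, 1 higher and 12 lower adjusted over the list alone, adjusted p = 1.06e-09, but adjusted p = 0.275 with an estimated correlation). Club cell genes were lower in 6 and higher in 1 of 11 (Cyp2f2, −0.76 ± 0.18; Cyp4b1, −1.01 ± 0.19; 1 higher and 8 lower adjusted over the list alone, adjusted p = 0.00035, but adjusted p = 0.275 with an estimated correlation). Cyp2f2, Cyp4b1 and Aldh1a7 were written into both the club cell and the xenobiotic metabolism list. Ciliated cell genes were lower in 2 of 15 (Tekt1, −0.40 ± 0.13; adjusted p = 0.0289, but adjusted p = 0.59 with an estimated correlation). Endothelial genes fell in 6 of 15, Kdr at −0.61 ± 0.15 (median −0.31, 8 lower adjusted over the list alone, adjusted p = 1.19e-05, but adjusted p = 0.275 with an estimated correlation). Alveolar type I genes fell in 5 of 10, Hopx at −0.47 ± 0.14 (6 lower adjusted over the list alone, adjusted p = 0.00035, but adjusted p = 0.275 with an estimated correlation). Circadian genes were lower in 4 and higher in 1 of 11, Bhlhe41 at −0.62 ± 0.15 (median −0.25, adjusted p = 0.0178, but adjusted p = 0.275 with an estimated correlation). Tekt1 lost its call without 7 different mice (highest adjusted p = 0.0692, without mouse656). Ciliated cell genes lost their call without 9 different mice (highest adjusted p = 0.0886, without mouse531) and in series 5 alone (adjusted p = 0.415), and circadian genes in series 6 alone (−0.27, adjusted p = 0.137). Club cell genes were at −0.21 in series 5 and −0.47 in series 6.

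Lists that were not called in C57BL/6J still held single genes that passed. Fibroblast and matrix genes were higher in 8 and lower in 1 of 16 (Col1a1, 1.22 ± 0.33; Timp1, 1.93 ± 0.40; 10 higher and 2 lower adjusted over the list alone, adjusted p = 0.0706), B and plasma cell genes in 3 and 1 of 16 (Irf4, 0.81 ± 0.19; Pou2af1, 0.59 ± 0.16), and complement genes in 5 and 1 of 10 (Cfb, 0.82 ± 0.22). Airway contraction genes were higher in 1 and lower in 6 of 26, with Agtr1a at −0.89 ± 0.19 and Plcb4 at −0.56 ± 0.13; their median was 0.01 and their test pointed down (adjusted p = 0.121). Smooth muscle genes had 1 of 11 lower (Cnn1, −0.85 ± 0.20; median −0.01). Eicosanoid genes split into 5 higher and 3 lower of 25 (Pla2g4c, 1.77 ± 0.38), and antioxidant genes into 1 and 4 of 16 (Nqo1, −0.67 ± 0.16). Marker genes of fat cells were lower in 2 of 7 (Adipoq, −0.92 ± 0.29) and of mesothelium in 2 of 7 (Krt19, −0.85 ± 0.19), while heart muscle genes had a median of −0.36 with 0 of 7 passing. Dendritic cell genes were higher in 3 of 11, alveolar type II genes lower in 2 of 14, neutrophil genes higher in 1 of 12, and NK and cytotoxic genes in 0 of 10. Adipoq lost its call without 2 different mice (highest adjusted p = 0.0606, without mouse643).

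**Figure D2:**
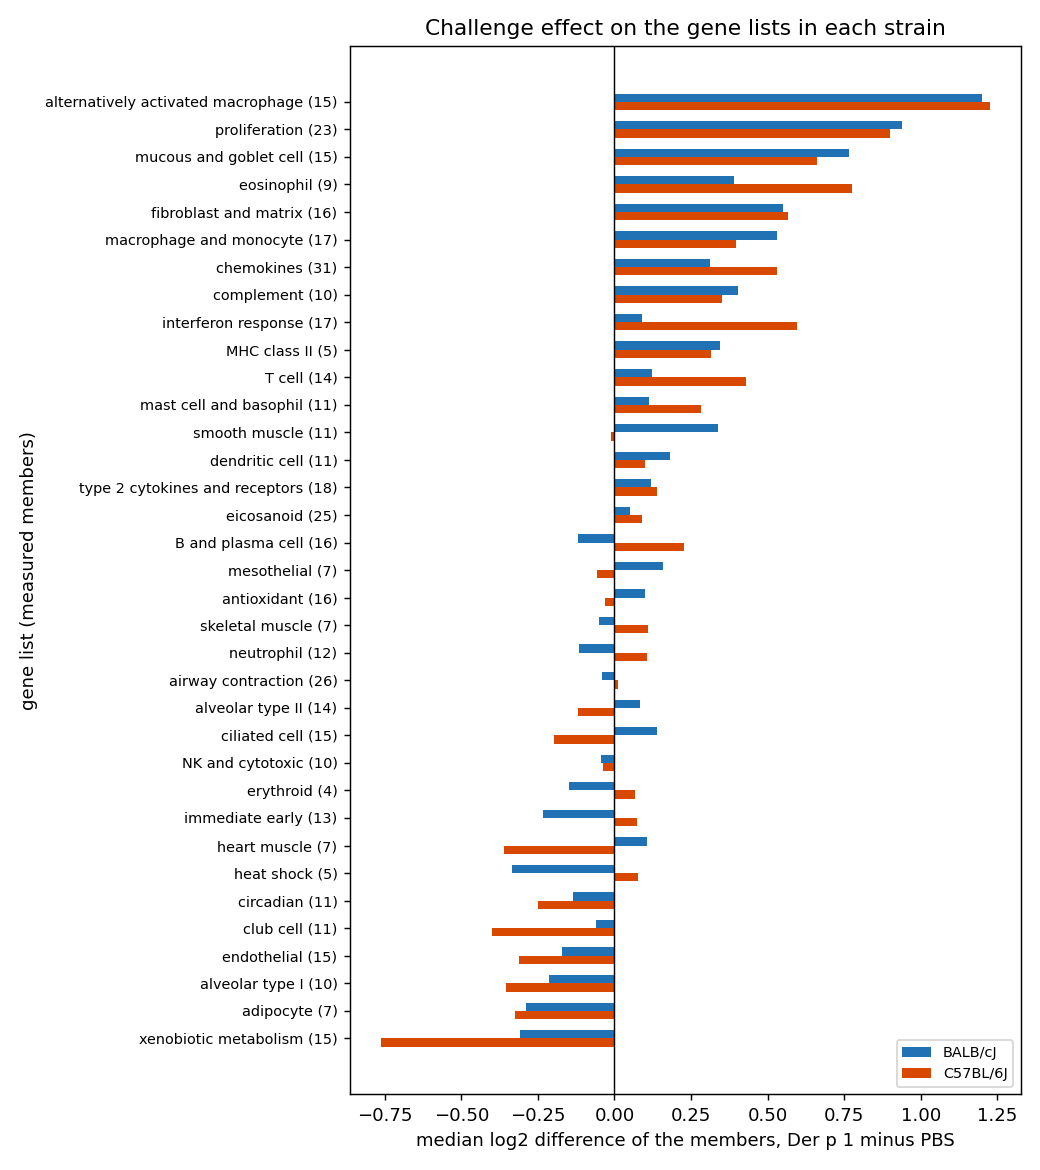
Median log2 difference of the members of 35 gene lists, challenged minus control, in BALB/cJ and C57BL/6J mice; each bar starts at 0 and stands for 1 list in 1 strain. Proliferation genes had medians of 0.94 and 0.90.

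Whether the strains responded in the same direction was asked by comparing the clusters past the threshold. The log2 differences of the strains rest on different mice, but all groups share 1 estimate of spread per cluster. A cluster with a small spread passes more easily in both strains, so the numbers expected of independent lists can be too low. Clca1, Chil4, Retnla, Slc26a4 and Ccna2 passed in both strains. A total of 221 clusters rose in both, against 28.0 expected, 31 fell in both, against 3.50 expected, and 0 passed in opposite directions. Without mouse633 and mouse634, 392 rose in both, against 54.3 expected, and 180 fell in both, against 23.2 expected. Of the 284 rises in BALB/cJ, 278 had the same sign in C57BL/6J, as did 38 of the 39 falls. Of the 1646 rises in C57BL/6J, 1357 had the same sign in BALB/cJ, as did 1418 of the 1500 falls. Over all 16715 clusters, which are not independent of each other, the log2 differences of the strains were correlated with r = 0.622.

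**Figure D3:**
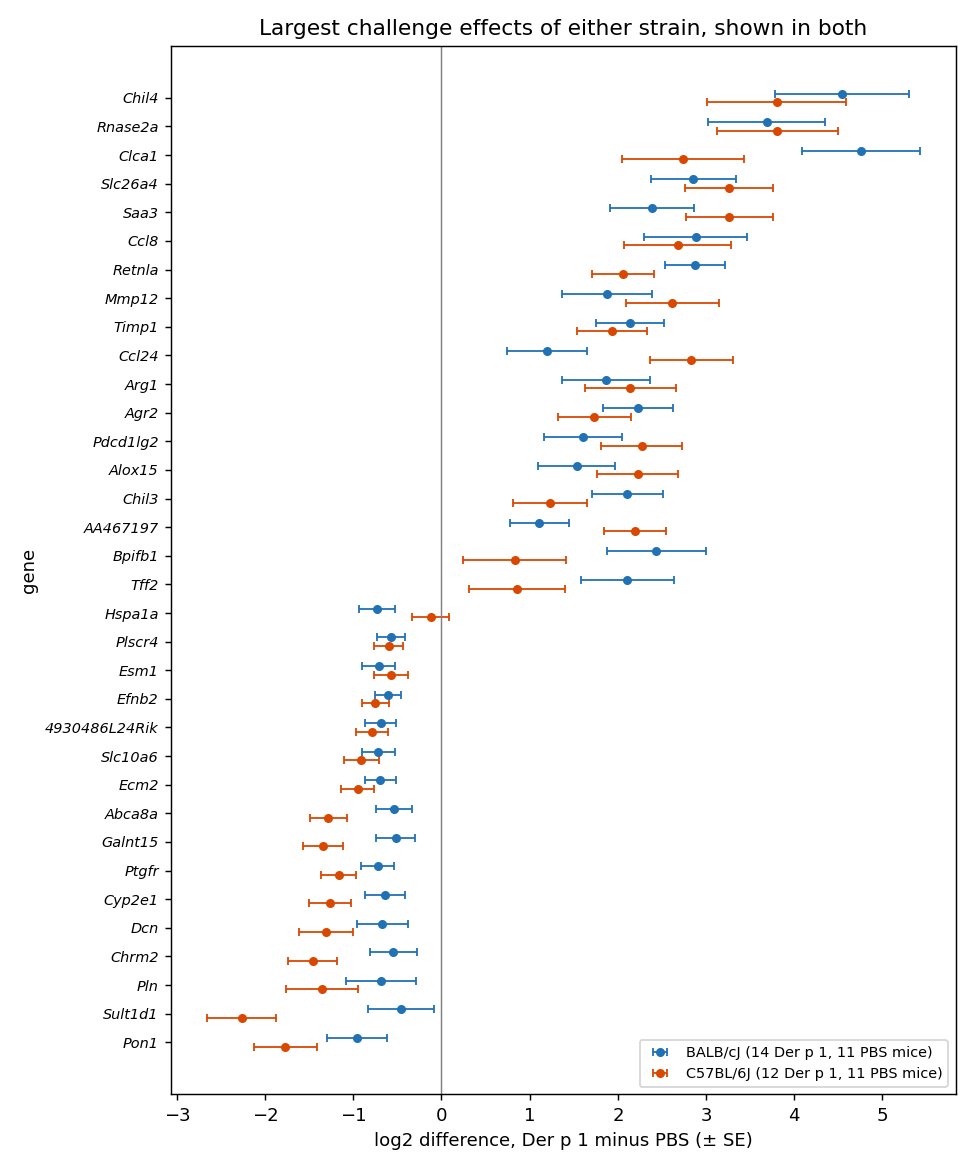
Log2 difference, challenged minus control, in C57BL/6J and in BALB/cJ for the named genes of either strain; points are estimates and bars their standard error. Clca1 lies at 2.74 ± 0.69 and 4.76 ± 0.67.

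The next question was which responses to Der p 1 differed between the strains, tested as BALB/cJ change minus C57BL/6J change. Fbp1, which encodes a gluconeogenic fructose bisphosphatase, was at 5.68 ± 0.22 in BALB/cJ controls and 5.72 ± 0.25 in challenged mice, and at 4.73 ± 0.28 and 5.96 ± 0.54 in C57BL/6J. Its changes differed by −1.19 ± 0.20 (adjusted p = 0.00351). Fcrl5, an Fc receptor-like gene of B cells, stayed at 4.27 ± 0.25 and 4.22 ± 0.14 in BALB/cJ and went from 4.18 ± 0.25 to 4.87 ± 0.27 in C57BL/6J, a difference of −0.73 ± 0.14 (adjusted p = 0.0177). Fcrl5 lost its call with the arrays quantile-normalized again (adjusted p = 0.155), with the first array of each mouse (0.0506) and with mouse as a random effect (0.0827). The C57BL/6J control level of Fbp1 and all group levels of Fcrl5 were low. The deposited values do not tell background from low expression, so the log2 differences of both genes are those of the deposited values. Neither gene was in the fit without the dimmest 50% of clusters, where 0 clusters passed by limma. Fbp1 was at −1.14 in series 5 and −1.18 in series 6 and passed in neither alone. Only these 2 clusters passed, against 1810 at an unadjusted p under 0.05, and 43.3% of simulated 1.5-fold differences were recovered by this test. The count was 0 by limma in series 5 (704 at an unadjusted p under 0.05), 2 in series 6 and 6 with the number series as a covariate. It was far larger with array weights (1759) and with the first residual component as a covariate (362). That component was taken from the residuals of the same fit, so it leaves the log2 differences unchanged and takes spread out of the tests. The count of 362 is therefore no support for a difference between the strains. Leaving out single mice, the count was 4 without mouse514, mouse532, mouse538 or mouse644, 5 without mouse534 and 6 without mouse647. Genes prominent in either strain did not pass this test, Clca1 at 2.02 ± 0.96, Ccl24 at −1.63 ± 0.66, Sult1d1 at 1.81 ± 0.54 and Prg2 at −0.85 ± 0.40. For Clca1 the rise in BALB/cJ was 4.05-fold that in C57BL/6J with all mice, 6.14-fold without mouse633 (adjusted p = 0.382) and 7.98-fold without mouse633 and mouse634 (adjusted p = 0.171). It was 3.11-fold without mouse644, a C57BL/6J control with Clca1 at 12.7 (adjusted p = 0.571). Challenged levels in series 5 and 6 were 11.6 and 11.1 in BALB/cJ and 11.9 and 11.4 in C57BL/6J. Control levels were 6.32 and 6.82 in BALB/cJ and 7.74 and 9.79 in C57BL/6J. Without mouse633 and mouse634 the BALB/cJ levels in series 6 were 11.8 in challenged mice and 5.67 in controls. Besides mouse644, the C57BL/6J controls mouse643, mouse645 and mouse655 of series 6 were at 10.6, 10.9 and 10.9, while mouse656 and mouse657 were at 7.73 and 5.96.

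As lists, 13 of 35 differed in their response by camera with a preset correlation, and 0 with an estimated correlation or by fry. Xenobiotic metabolism genes had a median of 0.46 (Aldh3a1, 1.02 ± 0.27; 4 of 15 higher adjusted over the list alone; adjusted p = 9.97e-10, but adjusted p = 0.311 with an estimated correlation). Smooth muscle genes had a median of 0.47 (Actg2, 0.99 ± 0.32; Cnn1, 0.93 ± 0.28; 6 of 11 higher adjusted over the list alone; adjusted p = 1.85e-06, but adjusted p = 0.386 with an estimated correlation). Interferon response genes had −0.45 (Oasl2, −0.73 ± 0.27; Mx2, −0.82 ± 0.29; adjusted p = 0.000101, but adjusted p = 0.516 with an estimated correlation). T cell genes had −0.29 (Lat, −0.51 ± 0.20; adjusted p = 0.00378, but adjusted p = 0.516 with an estimated correlation), and eosinophil genes −0.39 (adjusted p = 0.029, but adjusted p = 0.516 with an estimated correlation). The medians were 0.45 for club cell (adjusted p = 0.000116, but adjusted p = 0.386 with an estimated correlation) and 0.32 for ciliated cell genes (adjusted p = 6.07e-06, but adjusted p = 0.404 with an estimated correlation). For alveolar type II genes it was 0.16 (adjusted p = 0.00264, but adjusted p = 0.404 with an estimated correlation), and for endothelial genes 0.16 (adjusted p = 0.0117, but adjusted p = 0.516 with an estimated correlation). For fibroblast and matrix genes the median was 0.20 (adjusted p = 0.0185, but adjusted p = 0.516 with an estimated correlation), and for antioxidant genes 0.20 (adjusted p = 0.0164, but adjusted p = 0.386 with an estimated correlation). For heart muscle genes it was 0.51 (adjusted p = 0.0185, but adjusted p = 0.516 with an estimated correlation) and for mesothelial genes 0.36 (adjusted p = 0.0318, but adjusted p = 0.516 with an estimated correlation). In each of these lists 0 single genes passed over all genes.

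Of these 13 lists, 11 were called in series 5 alone and 6 in series 6 alone. Eosinophil genes were called in neither (adjusted p = 0.0835 and 0.175), and mesothelial genes were at 0.04 in series 5 (adjusted p = 0.619) and 0.80 in series 6. Alveolar type II (0.16, adjusted p = 0.0758), endothelial (0.16, adjusted p = 0.206), fibroblast and matrix (0.09, adjusted p = 0.505), interferon response (−0.46, adjusted p = 0.0783), antioxidant (0.23, adjusted p = 0.0758) and heart muscle genes (0.42, adjusted p = 0.206) were not called in series 6. Club cell genes were at 0.11 in series 5 and 0.37 in series 6. Leaving out single mice ended the calls of eosinophil (9 mice, highest adjusted p = 0.115 without mouse633), mesothelial (8 mice, 0.0775, mouse657), heart muscle (6 mice, 0.0986, mouse619) and fibroblast and matrix genes (0.0968, mouse647 alone). Medians moved to −0.22 for eosinophil and 0.10 for endothelial genes without mouse659, 0.31 for heart muscle genes without mouse619 and 0.23 for mesothelial genes without mouse657. Interferon response genes were at −0.24 without mouse646 and mouse649 (adjusted p = 0.0372).

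Without a challenge, the question was how control lungs of the strains differed, as BALB/cJ minus C57BL/6J. H2-Ea, the MHC class II E alpha chain that C57BL/6J lacks, was at 4.87 ± 0.94 in C57BL/6J and higher in BALB/cJ by 6.13 ± 0.35 (adjusted p = 1.91e-19, 11 of 11 mice). The level in C57BL/6J can be background, so no fold is printed for H2-Ea. Its log2 difference is that of the deposited values, and the difference in transcript may be larger. Muscle-type Fbp2 (2.60 ± 0.14), the cytokine gene Il1a (2.16 ± 0.28), Baiap2l1 (1.98 ± 0.11), Gatm (1.89 ± 0.29) and Atp13a4 (1.83 ± 0.15) were higher in BALB/cJ, as were Tmem252 (adjusted p = 8.32e-13) and Ctse (adjusted p = 4.10e-08). Scoc (−3.29 ± 0.23), the calcification inhibitor Mgp (−2.49 ± 0.15), Nxpe4 (−2.45 ± 0.16), H2-Ab1 (4.01-fold), Metap2 (−1.99 ± 0.10), Pttg1 (−1.96 ± 0.15) and Azgp1 (−1.88 ± 0.17) were lower, with Bpifb1 lower in 10 of 11 mice (adjusted p = 0.0184). Bpifb1 lost its call without mouse619 (0.0521), mouse620 (0.0518) or mouse644 (0.0517) and in each number series alone. Nnt, truncated in C57BL/6J, was at 8.96 ± 0.13 against 7.87 ± 0.10. Of 16715 clusters 779 passed, 318 higher and 461 lower in BALB/cJ, with 141 and 219 at least 1.5-fold; 275 passed in series 5, 694 in series 6 and 1126 with the number series as a covariate. Probes over sequence differences between the strains can give such calls, and whether they were masked is not given in the sources used here.

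MHC class II genes, H2-Ea not among them, were lower in BALB/cJ controls in 4 of 5, H2-Aa at −1.27 ± 0.16 and Cd74 at −1.13 ± 0.17 (median −1.13, 5 lower adjusted over the list alone, adjusted p = 1.29e-14, and 0.00349 with an estimated correlation). Probes over sequence differences between the strains can give such a list call too, and this was not tested. Ciliated cell genes were lower in 4 of 15 (11 adjusted over the list alone), Ccdc39 at −0.71 ± 0.15 (adjusted p = 1.79e-10, but adjusted p = 0.178 with an estimated correlation). Club cell genes were lower in 2 of 11, Scgb3a2 at −0.94 ± 0.20 (4 lower adjusted over the list alone, adjusted p = 0.000191, but adjusted p = 0.367 with an estimated correlation). Alveolar type II genes were lower in 2 of 14, Scd1 at −0.53 ± 0.14 (3 lower adjusted over the list alone, adjusted p = 0.00135, but adjusted p = 0.367 with an estimated correlation). Alternatively activated macrophage genes were lower in 4 of 15, Retnla at −1.25 ± 0.36 (5 lower adjusted over the list alone, adjusted p = 0.0124, but adjusted p = 0.895 with an estimated correlation). Xenobiotic metabolism genes were lower in 2 of 15, Gsto1 at −1.31 ± 0.23 (3 lower adjusted over the list alone, adjusted p = 0.00106, but adjusted p = 0.606 with an estimated correlation). Interferon response genes were lower in 1 of 17, Bst2 at −0.74 ± 0.17 (3 lower adjusted over the list alone, adjusted p = 0.00242, but adjusted p = 0.895 with an estimated correlation). Among 26 airway contraction genes, 3 were higher in BALB/cJ: Bdkrb2 (1.30 ± 0.16), Rgs5 (0.62 ± 0.12) and Chrm3 (0.48 ± 0.12), although the list was not called (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0658). Retnla lost its call without 9 different mice (highest adjusted p = 0.0786, without mouse644). Interferon response genes were at −0.08 in series 5 alone (adjusted p = 0.153) and −0.31 in series 6.

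**Figure D4:**
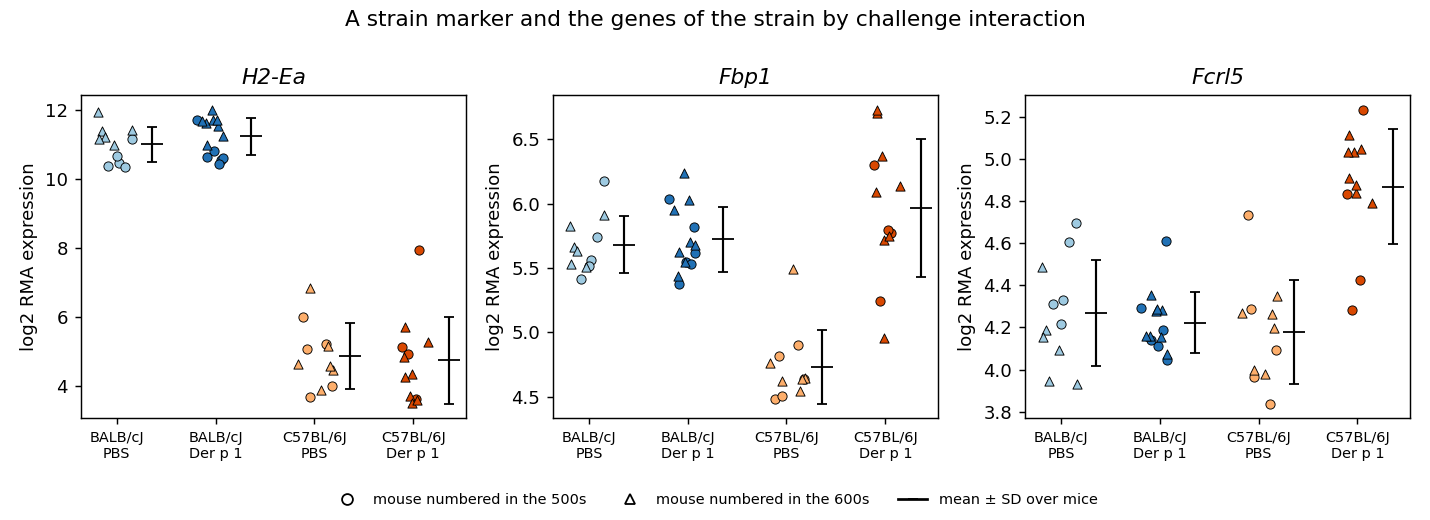
Deposited log2 values of H2-Ea, Fbp1 and Fcrl5 in each mouse, by strain and challenge, with bars for the mean ± SD. H2-Ea was higher in BALB/cJ controls by 6.13 ± 0.35 (log2 ± standard error).

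After Der p 1, the strain question was asked again in 14 BALB/cJ and 12 C57BL/6J mice. H2-Ea stayed far higher in BALB/cJ (6.48 ± 0.32, 14 of 14 mice), with Fbp2 (2.26 ± 0.13), Ctse (2.09 ± 0.23), Baiap2l1 (2.02 ± 0.10), Veph1 (2.01 ± 0.12), Angptl7 (1.75 ± 0.17), Fhl5 (1.65 ± 0.14) and Ifi202b (1.65 ± 0.21), the last at 0.55 and not past the threshold in series 5 alone. Ly6i was at 5.92 ± 0.43 against 8.52 ± 1.10 (−2.59 ± 0.25, adjusted p = 3.19e-11), and the antiviral deaminase Apobec3 at 7.11 ± 0.27 against 8.98 ± 0.27 (adjusted p = 1.86e-20). Scoc (−2.67 ± 0.21), Mgp (−2.24 ± 0.14), Metap2 (−2.14 ± 0.10), Nxpe4 (−2.04 ± 0.15), AA467197 (−2.04 ± 0.33) and Ly6d (adjusted p = 4.75e-08) were lower too. In this comparison 2222 clusters passed, 1073 higher and 1149 lower in BALB/cJ, with 214 and 245 at least 1.5-fold. The share that was lower, 51.7%, was 36.3% with each array centred on its median. In series 5 alone, 219 passed, in series 6 alone, 3560, and 4509 with the number series as a covariate. The strains differed in the same direction before and after challenge in 538 clusters, against 52.1 expected, and 0 passed in opposite directions. Both comparisons share 1 estimate of spread per cluster, so this number expected of independent lists can be too low.

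Interferon response genes were lower in challenged BALB/cJ mice in 13 of 17, Oasl2 at −1.17 ± 0.18, Bst2 at −1.07 ± 0.15 and Gbp3 at −0.96 ± 0.18 (14 lower adjusted over the list alone, adjusted p = 3.77e-09, but adjusted p = 0.478 with an estimated correlation). Of the C57BL/6J mice, mouse646 (2.14) and mouse649 (1.35) stood apart in this list's score from the other 10 challenged mice (−0.18 to 0.74). Without them 8 of 17 genes were lower and the median went from −0.71 to −0.38 (adjusted p = 1.93e-06, but adjusted p = 0.402 with an estimated correlation), with Oasl2 at −0.92, Bst2 at −0.87 and Gbp3 at −0.72. MHC class II genes were lower in 4 of 5, H2-Ab1 at −1.83 ± 0.18 (median −1.14, 5 lower adjusted over the list alone, adjusted p = 1.48e-08, and 0.0421 with an estimated correlation). As in controls, probes over sequence differences between the strains can give this list call. Airway contraction genes were higher in 8 of 26 (9 higher and 1 lower adjusted over the list alone), with the bradykinin receptor Bdkrb2 at 0.93 ± 0.14, Rgs4 at 0.80 ± 0.17 and Rgs5 at 0.73 ± 0.11 (median 0.13, adjusted p = 0.00629, and 0.0201 with an estimated correlation). Smooth muscle genes were higher in 3 of 11, Actg2 by 1.09 ± 0.22 and Cnn1 by 0.80 ± 0.19 (median 0.37, 5 higher adjusted over the list alone, adjusted p = 0.000134, but adjusted p = 0.555 with an estimated correlation). Endothelial genes were higher in 4 of 15 (Kdr, 0.51 ± 0.14; 6 higher adjusted over the list alone, adjusted p = 0.00133, but adjusted p = 0.555 with an estimated correlation). Fibroblast and matrix genes were higher in 4 of 16 (Lum, 0.91 ± 0.25; 5 higher adjusted over the list alone, adjusted p = 0.0105, but adjusted p = 0.681 with an estimated correlation). Xenobiotic metabolism genes were higher in 1 of 15 (Cyp2e1, 0.81 ± 0.22; adjusted p = 0.0105, but adjusted p = 0.744 with an estimated correlation). Without being called as lists, B and plasma cell genes had 5 of 16 lower (Cr2, −0.71 ± 0.21; Blk, −0.68 ± 0.15) and chemokine genes 5 of 31 (Ccl17, −1.29 ± 0.32; Cxcl10, −1.17 ± 0.27). Smooth muscle genes were at 0.14 in series 5 (adjusted p = 0.0971) and 0.46 in series 6, and in series 6 fibroblast and matrix (0.19) and xenobiotic metabolism genes (0.30) were not called (adjusted p = 0.0742 for both). Fibroblast and matrix genes lost their call without mouse647 (median 0.10, adjusted p = 0.0747) and xenobiotic metabolism genes without mouse659 (0.23, adjusted p = 0.0859), and the airway contraction median was 0.08 without mouse659.

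How reliable a single array was could be read from the 7 mice measured on 3 arrays each. Repeat arrays of a mouse correlated at a median of 0.984 over 21 pairs (0.968 to 0.994), and arrays of different mice of a group at 0.971 over 449 pairs. Of the 21 arrays of these mice, 13 matched an array of their own mouse best. For the median cluster the SD was 0.190 between repeat arrays and 0.294 between mice, a ratio of 1.51, and 87.9% of clusters had the larger spread between mice. The SD between mice also holds array error and the difference between the number series, so it is not spread between animals alone. Of the mice with repeats, mouse631 alone is of series 6, and 0 are C57BL/6J controls. H2-Ea and Nnt parted the strains without overlap, with H2-Ea in mouse532, a challenged C57BL/6J mouse, at 7.92 and all other C57BL/6J mice below that. Ifi202b overlapped, at 4.63 in mouse532 and 4.01 in mouse518 of BALB/cJ. The Y-linked genes Eif2s3y and Kdm5d were at 5.85 and 5.48 in mouse522, a BALB/cJ control, below all other mice.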

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

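The tests of mouse633 and mouse634, of mouse646 and mouse649, of the larger count in C57BL/6J and of array spread, and the regroupings within the number series, were chosen only after the results were seen; the other tests by regrouping the mice were chosen before any regrouping was fitted. The genes and lists named next were called by a test of the difference in response between the strains, the genes by limma and the lists by camera with the preset correlation. By the other tests run, camera with an estimated correlation (lowest adjusted p = 0.311) and fry (lowest adjusted p = 0.173), 0 lists were called. Fbp1 differed by −1.19 and Fcrl5 by −0.73 in their response, BALB/cJ change minus C57BL/6J change. Fbp1 in C57BL/6J controls and Fcrl5 in every group were at low levels, where background cannot be told from low expression. As medians of gene lists the differences were −0.39 for eosinophil, −0.29 for T cell, −0.45 for interferon response, 0.45 for club cell, 0.32 for ciliated cell, 0.16 for alveolar type II, 0.16 for endothelial, 0.47 for smooth muscle, 0.20 for fibroblast and matrix, 0.20 for antioxidant, 0.46 for xenobiotic metabolism, 0.51 for heart muscle and 0.36 for mesothelial genes. In series 5 alone 11 of these 13 lists were called and in series 6 alone 6, with mesothelial genes at 0.04 and 0.80, club cell genes at 0.11 and 0.37, and fibroblast and matrix genes at 0.29 and 0.09. Without mouse646 and mouse649, which stood apart among challenged C57BL/6J mice, interferon response genes were at −0.24 (adjusted p = 0.0372).

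Chance as a source of the cluster counts was weighed with 100 groupings of the same mice, the real one included. Few groupings gave as many calls as the real one, which argues against chance, but 100 groupings cannot exclude it. In BALB/cJ 2 groupings gave as many (323 in the real one, 411 in the highest other). In C57BL/6J 1 did (3146 against 4), in the interaction 1 (2 against 0), in controls 1 (779 against 116) and in challenged mice 1 (2222 against 743). The grouping with 411 put 10 mice of series 6 among its 14, and the grouping with 743 put 11 there. Splitting the 25 BALB/cJ mice by number series, 14 against 11, gave 5610 clusters, several times the real count, which points to a structure of the samples. Within series 5 the BALB/cJ count was 133 and within series 6 it was 0 by limma (1834 at an unadjusted p under 0.05). Without mouse633 and mouse634, both of series 6, the count in series 6 was 923. With the series as a covariate and all mice it was 538.

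Groupings free to differ in their mix of the 2 number series can hold a difference between the series, so 100 groupings that kept the number of mice of each group within each series were fitted too. Here too few groupings gave as many clusters, which argues against chance without excluding it. The real grouping included, 1 gave as many in BALB/cJ (highest other 0), 1 in C57BL/6J (2640), 2 in the interaction (44), 1 in controls (43) and 2 in challenged mice (4763). The groupings with 2640 and 4763 had the largest difference in mean array SD of the 99 others in their comparison (1.98 against 1.83, and 1.84 against 1.99), which points to array spread as a structure of the samples. With array SD as a covariate the real counts were 2279 in C57BL/6J and 1791 in challenged mice.

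For the number of gene lists called with the preset correlation, the groupings do not argue against chance, which stays open in every comparison. In BALB/cJ 18 of 100 groupings gave as many (18 lists, highest other 22), in C57BL/6J 26 (14; 21), in the interaction 27 (13; 24), in controls 65 (7; 19) and in challenged mice 78 (7; 23). Within the number series 8 groupings gave as many in BALB/cJ (highest other 23), 22 in C57BL/6J (20), 25 in the interaction (21), 61 in controls (17) and 72 in challenged mice (20). Single lists fared differently: proliferation, mucous and goblet cell and alternatively activated macrophage genes had 1 grouping as large, the real one, in each strain's response, within the series as well.

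In the BALB/cJ mice of series 6, mouse633 is listed as a control and mouse634 as challenged, and both went against their group. Over 358 genes chosen in C57BL/6J alone, mouse633 scored 6.79 (the other 13 challenged mice 6.01 to 7.06) and mouse634 5.77 (the other 10 controls 5.58 to 5.89), so 2 of the 2 mice lay within the range of the other group. A failed or compressed array is argued against, since 0 of the 2 had an array SD outside the range of the other BALB/cJ mice (1.98 and 2.06 within 1.74 to 2.09). An exchange of labels or tissue between the 2 mice is thus a candidate explanation. That each mouse responded in its own way stays open and was not tested, and both mice were kept under their labels.

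More clusters passed in C57BL/6J than in BALB/cJ, by a ratio of 9.74. Without mouse633 and mouse634 the ratio was 3.91 (2.62 to 5.69 over the mice left out in turn), and with array SD as a covariate 3.05 (1.79 to 4.69), which argues against either as the whole source. With both changes the ratio was 1.53 (1.01 to 1.98), so a stronger response of C57BL/6J and the 2 mice together with array spread cannot be told apart, because the range reaches close to equal counts. The difference of strain itself stays open and untested, and a count of clusters past a threshold is no measure of the size of a response.

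Of the 13 gene lists called in the interaction with the preset correlation, 9 were called in the same direction with array SD as a covariate and 11 without mouse633 and mouse634, which argues against array spread and against the labels of the 2 mice as the whole source. With array SD the medians were 0.04 for alveolar type II, 0.09 for endothelial, 0.06 for antioxidant and −0.10 for mesothelial genes, none called; without the 2 mice eosinophil genes (−0.34) and mesothelial genes (0.22) were not called, and interferon response genes moved from −0.45 to −0.59 with array SD (adjusted p = 1.93e-13). For the number of lists chance stays open, as 27 of 100 groupings gave as many (25 within the number series), and 0 lists were called with an estimated correlation or by fry. List by list, 1 grouping gave as large a mean for xenobiotic metabolism (0.62) and smooth muscle genes (0.47), 2 for club cell and for interferon response genes, 4 for antioxidant genes and 5 or more for the other 8, and within the series 1 for the first 4, 3 for ciliated cell, 4 for T cell and antioxidant genes, and 7 or more for the other 6. A response that differs with strain is the explanation the design names, and it was not tested apart from these.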

How the results depend on the processing

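The fits without mouse633 and mouse634, without mouse646 and mouse649 and with array SD, alone or combined, and the gene lists within each number series were chosen only after the results were seen; the other alternatives were chosen before the data were examined. Values were deposited after RMA, so background signal could not be told from low expression, and dim clusters may hold no transcript signal: with the dimmest 50% left out the counts were 134 in BALB/cJ, 2157 in C57BL/6J, 0 in the interaction (617 at an unadjusted p under 0.05 by limma), 402 in controls and 1497 in challenged mice, and with the dimmest 25% left out the interaction held 1. Leaving out 1 mouse at a time gave 215 to 614 in BALB/cJ, 2224 to 4969 in C57BL/6J, 2 to 6 in the interaction, 678 to 852 in controls and 1706 to 3196 in challenged mice. No paired analysis was possible because no label links a control to a challenged mouse. The first residual component was taken from the residuals of the same fit, so as a covariate it takes out spread and leaves the log2 differences unchanged. Its larger counts are therefore no support for the calls. Why the other settings moved a count is open: the cause was not tested.

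For treated vs control in BALB/cJ, the 323 clusters became 488 with mouse as a random effect, 1361 with array weights, 538 with the number series as a covariate, 133 in series 5, 0 in series 6 (1834 at an unadjusted p under 0.05 by limma) and 770 with the first residual component. Without mouse633 and mouse634 there were 809 (322 shared), with array SD 748, with both 1564, with the series and without the 2 mice 1247, and in series 6 without them 923; 197 were at least 1.5-fold. In C57BL/6J the 3146 became 7035 with array weights, 5480 with the series, 305 in series 5, 6440 with the residual component and 5394 with the series and without the 2 mice, and 788 were at least 1.5-fold.

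In the interaction the 2 became 1 with the first array of each mouse, 1759 with array weights, 6 with the series, 0 in series 5 (704 at an unadjusted p under 0.05 by limma), 362 with the residual component, 7 with the series and without the 2 mice and 12 in series 6 without them. For BALB/cJ vs C57BL/6J in controls, the 779 became 1765 with array weights, 275 in series 5, 1355 with the residual component, 1249 with array SD and 1268 with array SD and without the 2 mice, and 360 were at least 1.5-fold. Between challenged mice the 2222 became 4527 with array weights, 1438 with the compared groups only, 4509 with the series, 219 in series 5, 3560 in series 6, 5863 with the residual component and 3745 with the series and without the 2 mice, and 459 were at least 1.5-fold.

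Gene lists called in BALB/cJ went from 18 to 10 in series 5, 5 by fry and 4 with an estimated correlation. In C57BL/6J they went from 14 to 22 with array SD, 23 with array SD and without the 2 mice, and 0 with an estimated correlation (16 by fry). In the interaction they went from 13 to 7 in series 6, 7 with the dimmest 25% left out, and 0 by fry and with an estimated correlation. Between controls 7 became 11 without the 2 mice, 12 in series 6, 3 by fry and 1 with an estimated correlation. Between challenged mice 7 became 14 with array SD, 12 with array SD and without the 2 mice, 11 in series 5 and 2 with an estimated correlation.

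Single genes chosen by size gave 74 calls (20 in each challenge comparison, 2 in the interaction, 16 in each strain comparison). Of these, 0 turned direction in 66 fits to clusters, 48 of them without 1 mouse. Many of these fits could not turn a direction. Leaving out a mouse outside the compared groups keeps the log2 difference as it was. So do leaving out dim clusters, a trended prior, fitting the compared groups only and the residual component. Of the 74, 3 were not in the fit without the dimmest 25% and 27 not in that without the dimmest 50%. The calls lost were those of Fcrl5 with quantile normalization again, the first array of each mouse, mouse as a random effect, and array SD without the 2 mice, of Hspa1a without the 2 mice and with array weights, and of Hspa1a, Esm1 and 4930486L24Rik with the compared groups only. In series 6 without the 2 mice 6 were lost, and 19 in series 5 and 25 in series 6, the latter with all 20 of BALB/cJ. Without single mice, 9 of the 74 were lost, 8 of them in the BALB/cJ challenge. Of 213 further calls, of list members, 0 turned direction in these fits (13 and 71 were not in the fits without the dimmest 25% and 50%). Of these, 52 ended without some mouse, 36 with quantile normalization again, 13 with centring, 38 with the compared groups only, 35 with array SD, 11 without the 2 mice, 154 in series 5 and 70 in series 6. Without mouse646 and mouse649 the median of interferon response genes was 0.37 in C57BL/6J, −0.24 in the interaction and −0.38 between challenged mice, called in each. The ratio of spread between mice to spread between repeat arrays was 1.51, and 1.68 by median absolute deviation.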

Other observations

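The test of challenge by number series was chosen only after the values were seen. Among challenged BALB/cJ mice, the levels of some genes lay apart by number series when mouse633 and mouse634 were left out. These levels were not tested against each other. Clca1 was at 11.64 ± 0.84 in 6 challenged mice of series 5 and 11.80 ± 0.73 in 7 of series 6, and Top2a at 7.38 and 7.45. Arg1 was at 6.39 ± 1.15 against 8.79 ± 1.04, Ccl8 at 6.55 ± 1.58 against 9.04 ± 1.45, and Rnase2a at 6.88 against 9.88. Slc26a4 was at 7.45 against 9.24.

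Tested as a difference in the response between the series, without the 2 mice, 3 clusters passed in BALB/cJ, larger in series 6 (842 at an unadjusted p under 0.05); with all mice 0 passed by limma (630), and in C57BL/6J 0 passed (1210). Rnase2a (2.76 ± 0.80, adjusted p = 0.404), Arg1 (2.43 ± 0.72, adjusted p = 0.419), Ccl8 (2.34 ± 0.75, adjusted p = 0.522) and Slc26a4 (1.73 ± 0.67, adjusted p = 0.776) did not pass. Lists larger in series 6 also with an estimated correlation were type 2 genes (median 0.36, adjusted p = 0.00561), chemokines (0.84, 0.0155), alternatively activated macrophage (0.84, 0.0284), eosinophil (0.55, 0.0202), mast cell and basophil (0.31, 0.0284), macrophage and monocyte (0.54, 0.0308), dendritic cell (0.38, 0.0155), complement (0.51, 0.0284) and eicosanoid genes (0.36, 0.00507). Both mice left out are of series 6 and were left out because their values went against their labels. Leaving them out by itself enlarges the series 6 response, so the clusters and lists larger there are no independent support. With all mice and an estimated correlation, type 2 genes had an adjusted p of 0.0617, chemokines 0.112, eosinophil 0.322 and alternatively activated macrophage genes 0.74. Ciliated cell genes responded less in series 6 (−0.38, adjusted p = 0.0202), and with all mice they were the sole list to hold (−0.38, adjusted p = 0.0379). Proliferation genes (0.42, adjusted p = 8.33e-09, but adjusted p = 0.197 with an estimated correlation) and mucous genes (0.16, adjusted p = 0.012, but adjusted p = 0.396 with an estimated correlation) did not hold in BALB/cJ. In C57BL/6J 0 lists held with an estimated correlation (lowest adjusted p = 0.226): mucous genes were at −0.43 and alternatively activated macrophage genes at 0.18 (adjusted p = 0.796 with an estimated correlation). These are hypotheses found and tested in the same mice, and a batch of animals, time or arrays is not separated by the labels.

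Clca1 in C57BL/6J controls was at 7.74 in 5 mice of series 5 and 9.79 in 6 of series 6, reaching 12.7 in mouse644, where Chil4 was 10.4. In series 6 the controls mouse643, mouse645 and mouse655 were at 10.6, 10.9 and 10.9 as well, above the lowest challenged C57BL/6J mouse (10.1, mouse532). The other controls of series 6, mouse656 and mouse657, were at 7.73 and 5.96. Given challenge, the series differed in 7422 clusters in BALB/cJ and 5970 in C57BL/6J. Mouse522, a BALB/cJ control, had the lowest value of the Y-linked gene Eif2s3y (5.85), and mouse532, a challenged C57BL/6J mouse, had an array SD of 1.44, the lowest of all, beside H2-Ea at 7.92; both were kept under their labels.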
